A study of Mus musculus with 6 samples.

How the data were processed

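Poly(A)-enriched RNA libraries of infarcted mouse myocardium were sequenced, 3 labelled wild type and 3 labelled Itih5 knockdown, all from 7 days after infarction, per the labels. The labels' protocols name 2 library kits without saying which library was made with which. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier, the gene annotation and how the knockdown was made are not given in the sources used here.

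The authors deposited a table of 16205 rows, with a gene symbol and a value for each of the 6 libraries. The file's name describes the values as TPM (a length-corrected share of the reads that adds up to 1000000), but the deposited values are an adjusted score, not plain TPM. The columns sum to between 901563 and 1159657. Low values lie at whole multiples of a step that differs by library, from 0.889 to 1.163. Below 3.5 steps, 96.9% to 100% of values lay within 0.15 steps of a whole multiple, where 30% would by chance. Column sums divided by the step came to between 996826 and 1013982, as whole-number TPM that was later rescaled would give. What adjustment the authors applied between libraries is not stated in the sources used here. The steps are alike for all genes but for a slight spread and are therefore not single reads, so no count model was used and the sequencing depth is unknown. Rounding limits the precision of genes with low values. Between 212 and 1082 genes per library were listed at 0; the library labelled knockdown replicate 1, with the fewest, had 1078 values above 0 and under 0.2, where the others had 0.

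Of rows sharing a symbol, the one with the highest mean was kept and 6 were left out. A spreadsheet had turned 8 symbols into dates, and these rows belong to no gene list. Coordinates come from the GENCODE M21 annotation of the same build, which held 16018 of the 16199 symbols. No 2 libraries held identical values, and their Pearson correlations across all 16205 rows, which are not independent replicates, ran from 0.948 to 0.984 on the log2 scale. The mean correlations within and between groups given in the report are over the 14025 tested genes.

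Values were analysed as log2(value + 1) for the 14025 genes with a mean of at least 1 over the 6 libraries. Fold changes are on that scale, which understates changes of low genes. Groups were compared with the moderated test of limma 3.58.1 in R 4.3.3, with an intensity trend and Benjamini-Hochberg adjustment at 0.05, and with no covariate. The test had been planned for TPM, and was kept for the adjusted values. An exact two-sided permutation test was added for Itih5 and for the mitochondrial share. Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over 40 lists with at least 5 tested members. Each was tested again with a correlation estimated from these libraries and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Members were also counted as passing when adjusted over the list alone. A list's score in a library is the mean over its members of the log2 value minus that gene's mean over the 6 libraries.

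The 40 lists, 887 genes of which 846 are in the table, were written before the data were examined, from the study's subject and from markers of cell types that infarcted myocardium can hold. Some genes stand in several lists. They cover collagens, matrix glycoproteins, matrix crosslinking and turnover, myofibroblasts, resting fibroblasts, matrifibrocytes, the TGF-beta pathway and hyaluronan genes. Immune lists cover macrophages, inflammatory cytokines, reparative macrophages, monocytes, neutrophils, dendritic cells, T and natural killer cells, B cells, mast cells, interferon-stimulated genes, complement, engulfment and lysosome, NF-kB and STAT signalling, and apoptosis and pyroptosis. The others cover sarcomere, stress and fetal, atrial, ion channel, oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, endothelial, lymphatic, pericyte, epicardial, Schwann cell, adipocyte, skeletal muscle, erythroid, cell cycle, immediate early and ribosomal protein genes.

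The rule for naming genes was also set before the data were examined. It takes the Itih family and, in each direction, 12 genes past the threshold with a mean of at least 5 and groups that do not overlap, filled up by the smallest unadjusted p where fewer pass. It also takes up to 4 members of each list with the smallest p (6 for the collagen, myofibroblast, macrophage, cytokine and reparative macrophage lists), and genes that check library quality. Unnamed gene models, pseudogenes and immune receptor segments were skipped among the 12. Since no gene passed, all 24 come from the fill, where the mean of at least 5 and the absence of overlap were also asked for, a reading of the rule made after the data were seen.

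The fit was tested on simulated data with the means of the 14025 genes and the fitted spread, for the comparison of the libraries labelled knockdown with wild type. Among 200 changed genes it recovered 65% of the 100 changed by 1 and 92% of the 100 changed by 2 on the log2 scale, with 11 false calls among 168. A simulated list shifted by -0.5 was called and 0 of the other 39 lists were. Genes in that simulation were independent, unlike real ones.

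Alternatives were other pseudocounts (0.1 and 5), other filters (none, or a mean of at least 5), median-of-ratios and quantile scaling, and leaving out mitochondrial genes or the 50 most abundant genes. Others were no intensity trend, library quality weights, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Whole-number TPM recovered by dividing by the steps, and the heart muscle score as a covariate, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.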

Results

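RNA sequencing was carried out on infarcted mouse myocardium collected 7 days after ligation of the left anterior descending branch, the coronary artery tied off to cause a heart attack. Of the 6 libraries, 3 came from wild-type mice and 3 from mice labelled as having Itih5 knocked down. Itih5 encodes a heavy chain of the inter-alpha-trypsin inhibitor family, secreted proteins that bind hyaluronan in the matrix. The study asked whether ITIH5 influences scarring after infarction by acting on the immune response. Each library has a value for each gene on a scale close to TPM and 14025 genes were tested. The number of reads behind a value is unknown, because the table holds no counts. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

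Itih5 transcript was not lower in the libraries labelled Itih5 knockdown. Itih5 lies on the plus strand of chromosome 2, from 10153571 to 10256529 in mm10, and is annotated as protein coding. Its values were 9.73, 13.1 and 17.2 in wild-type replicates 1, 2 and 3, against 18.4, 10.5 and 19.96 in the libraries labelled knockdown. The means were 13.3 ± 3.75 (SD, n = 3) and 16.3 ± 5.06 (SD, n = 3). The fitted log2 difference, labelled knockdown minus wild type, was 0.26 (95% interval -0.39 to 0.90, limma adjusted p = 0.645). An exact two-sided permutation test gave p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow. The related genes Itih4 (log2 difference -0.27, SE 0.45), Itih2 (0.11, SE 0.15) and Itih3 (0.27, SE 0.24) did not pass the test either. Itih2 (2.68 to 3.46) and Itih3 (0.889 to 2.00) lay within a few rounding steps, so they can hardly show a difference. Itih2 was lowest where the step was smallest (0.889, wild-type replicate 3). It was highest where the step was largest (1.163, the library labelled knockdown replicate 1). Every direction below therefore refers to the labels, and the knockdown was not visible as a lower Itih5 transcript level.

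The 12 genes with the smallest p-values among those lower in the libraries labelled knockdown were of mixed function. Ccl2, which encodes a chemokine that recruits monocytes, was at 41.1, 42.4 and 52.1 in wild type and at 19.1, 21.1 and 24.9 in the libraries labelled knockdown (log2 difference -1.02, SE 0.14). Arg1, which encodes the arginine-degrading enzyme arginase 1 of alternatively activated macrophages, was at 52.8, 60.5 and 79.9 against 9.07, 15.2 and 26.9 (log2 difference -1.96, SE 0.35). Fcna, a ficolin gene expressed by macrophages, had a log2 difference of -2.18 (SE 0.42), and the chemokine gene Ccl6 had -1.34 (SE 0.27). The other 8 were Tmem8 (-0.95), Tbc1d13 (-0.54), Pctp (-0.58), Chst11 (-0.74), Pmvk (-0.55), the glutathione reductase gene Gsr (-0.53), the DNA repair gene Apex1 (-0.61) and Arf6 (-0.51).

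On the higher side, the 12 genes with the smallest p-values were of mixed function. Mdm4, which encodes a negative regulator of p53, was at 25.3, 29.0 and 21.3 in wild type and at 44.8, 40.5 and 45.9 in the libraries labelled knockdown (log2 difference 0.78, SE 0.13). The phosphate transporter gene Slc20a1 had a log2 difference of 0.86 (SE 0.14) and the interleukin 15 receptor gene Il15ra had 0.80 (SE 0.13). Fgfbp3 (0.90), the long non-coding RNA Airn (0.94), Zmym6 (0.76), Trim7 (0.97), Trim11 (0.53), Trim39 (0.61), Srek1 (0.67), Zfp950 (0.77) and Dusp11 (0.50) made up the rest.

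None of these genes passed the test. With limma, 0 genes were higher and 0 lower after Benjamini-Hochberg adjustment over all genes, and the smallest adjusted p was 0.296, which all 24 of these genes share. At an unadjusted p under 0.05 there were 2081 genes (1162 higher and 919 lower), where chance alone would give about 701. The groups did not overlap for 3147 genes, or 22.4% of those tested, where chance gives 10%. This and every absence of overlap below refers to the deposited values, whose scale between libraries follows an unknown adjustment. Without wild-type replicate 1, 660 genes were higher and 338 lower at that unadjusted p, and without wild-type replicate 3, 655 and 386; without the library labelled knockdown replicate 1, 543 were lower. Without wild-type replicate 2, 2 genes passed as lower, and without the library labelled knockdown replicate 3, 13 did, among them Fcna, Ccl6, Ighm and the adipocyte genes Cfd, Adipoq, Cidec and Car3.

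**Figure D1:**
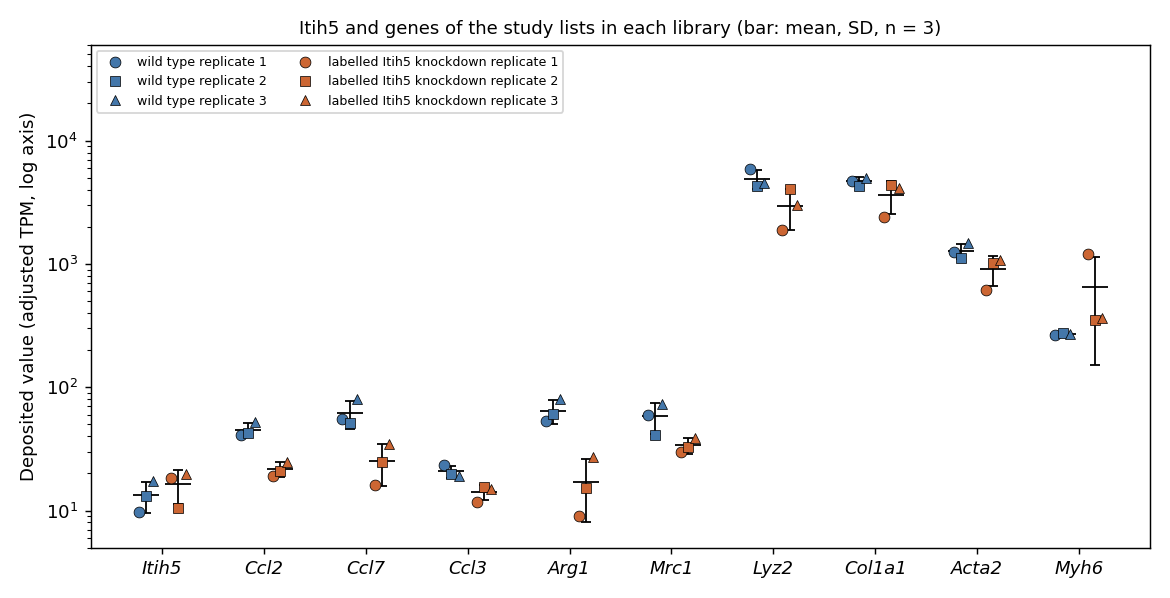
Deposited values of 10 genes in each library on a log axis, with wild type in blue and the libraries labelled Itih5 knockdown in orange; symbols give the replicate number and bars the mean and SD of 3 libraries. Itih5 overlaps between the groups, whereas Ccl2 lies between 41.1 and 52.1 in wild type and between 19.1 and 24.9 in the libraries labelled knockdown, and Myh6 reaches 1214 in the library labelled knockdown replicate 1.

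Inflammatory chemokine and cytokine genes were lower as a group in the libraries labelled knockdown, 23 of 25 tested members having a lower mean and the median log2 difference being -0.41. Besides Ccl2, the monocyte and neutrophil attractants Ccl7 (log2 difference -1.29, SE 0.29), Ccl9 (-0.99, SE 0.22) and Ccl3 (-0.53, SE 0.13) passed when adjusted over the list alone, 4 members in all, against 0 over all genes tested. Il6 fell short of that test, at 12.7, 10.3 and 9.97 in wild type and 7.08, 8.67 and 7.98 in the libraries labelled knockdown, as did Ccl8 (log2 difference -1.49, SE 0.48). The list test (camera with a preset correlation between genes) gave an adjusted p of 1.37e-05 over the 40 lists. With an estimated correlation the adjusted p was 0.668. The number of members past the test over the list alone was 1 when any single wild-type library was left out, 3 without the library labelled knockdown replicate 1, 8 without the library labelled knockdown replicate 2, and 6 without replicate 3 of that group. Without replicate 1 of that group the median of the list was -0.24.

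Macrophage genes pointed the same way. All 24 members of the general macrophage list were lower on average, with a median log2 difference of -0.55. Lyz2, the macrophage lysozyme gene, was at 5899, 4269 and 4553 in wild type and at 1877, 4049 and 3001 in the libraries labelled knockdown (log2 difference -0.78, SE 0.31). The F4/80 gene Adgre1 (-0.92), Laptm5 (-0.74), the Fc receptor gene Fcgr1 (-0.84) and the growth factor receptor gene Csf1r (-0.55) did not overlap between the groups either. None of the 24 passed the test, whether over all genes or adjusted over the list alone. As a list they had an adjusted p of 1.12e-07, and 0.668 with an estimated correlation. The mean score of the list was 0.50, 0.20 and 0.12 in wild type and -0.80, 0.02 and -0.04 in the libraries labelled knockdown, lowest in replicate 1 of that group, and without that library the median was -0.28.

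Genes of reparative macrophages, the state that clears debris and builds scar, were lower for 19 of 24 tested members (median log2 difference -0.52, adjusted p = 2.59e-05, and adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 6 members passed, against 0 over all genes. Of these, Arg1, Cbr2 (log2 difference -1.17, SE 0.27), the interleukin 4 receptor gene Il4ra (-0.51, SE 0.13), the mannose receptor gene Mrc1 (-0.73, SE 0.21) and the scavenger receptor gene Msr1 (-0.80, SE 0.24) were lower. Vegfa, the angiogenic growth factor gene that heart muscle also expresses, was higher, at 43.9, 48.7 and 35.2 against 208, 73.0 and 75.9. This count is fragile: it was 0 without wild-type replicate 1 or 3, 3 without the library labelled knockdown replicate 1, 1 with mitochondrial genes left out, and 9 without replicate 3 of the labelled knockdown group. The median of the list was -0.34 without the library labelled knockdown replicate 1.

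Genes of engulfment and the lysosome were lower for 20 of 23 members (median -0.27, adjusted p = 1.25e-05), including the lysosomal genes Lipa (-0.48) and Npc2 (-0.59) and the integrin gene Itgb3 (-0.57). Interferon-stimulated genes were lower for 25 of 29 (median -0.30, adjusted p = 1.82e-05), with Oas3 at -1.02, Ifit3b at -0.72, Oas1a at -0.64 and Isg15 at -0.66. Monocyte genes were lower for 15 of 17 (median -0.41, adjusted p = 0.000450), among them Ms4a6c (-0.99), Ifi204 (-0.78) and Plac8 (-1.15). Hp, on the same list, overlapped between the groups at 178, 662 and 413 against 7.51, 28.5 and 330, and followed the adipocyte gene Cfd (285, 810 and 402 against 1.44, 3.47 and 852). All 14 neutrophil genes tested were lower (median -0.72, adjusted p = 0.000450), and Lcn2, the lipocalin gene, passed adjusted over the list alone (-1.05, SE 0.24), as the only 1 of the 14, with Trem1 (-0.99), Il1r2 (-0.69) and Mmp9 (-1.35) short of it. For the complement list, 16 of 20 were lower (median -0.52, adjusted p = 0.000978), with Cfi at -0.78, C3ar1 at -0.63 and Itgb2 at -0.64, whereas the complement inhibitor gene Cd55 was at 0.34. For B cells, 19 of 20 were lower (median -0.97, adjusted p = 1.82e-05), and the immunoglobulin gene Ighm was at 728, 624 and 1170 against 45.1, 54.4 and 446. Igkc (-1.27), Cd79a (-1.86) and Fcmr (-1.53) overlapped between the groups. The B cell score was 0.39, 0.02 and 1.17 against -1.02, -1.08 and 0.52, low in the same libraries labelled knockdown, replicates 1 and 2, as the adipocyte score (-1.49 and -1.74, against 1.29 in replicate 3) and the mesothelial score (-1.38 and -0.60, against 0.77). With an estimated correlation the adjusted p of each of these 6 lists was 0.668. Members past the test over their list alone moved with single libraries: without the library labelled knockdown replicate 3 there were 16 B cell, 9 complement, 7 monocyte and 5 neutrophil genes, without replicate 2 of that group 7 interferon-stimulated genes, and 0 neutrophil genes without wild-type replicate 1 or 3 or the library labelled knockdown replicate 1 or 2. Without that replicate 1 the medians were -0.16 for engulfment, -0.27 for interferon-stimulated, -0.27 for monocyte, -0.45 for neutrophil, -0.25 for complement and -0.76 for B cell genes. With the heart muscle score as a covariate, an alternative added after the values were seen, the neutrophil (0.0705) and complement calls (0.157) were lost, as was the neutrophil call among genes with a mean of at least 5 (0.0570).

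T and natural killer cell genes (median -0.19, adjusted p = 0.0647) and dendritic cell and MHC class II genes (median -0.08, adjusted p = 0.504) were not called as lists, and the cytotoxic gene Gzma was at -0.80. Clec9a (0.85) and Zbtb46 (0.70), both genes of conventional dendritic cells, were higher without overlap in the deposited values but did not pass. The gap between the groups was about that of the steps. Clec9a was at 5.65 in wild-type replicate 2 (step 0.932) and 5.78 in the library labelled knockdown replicate 2 (step 0.959). Zbtb46 was at 7.96 in wild-type replicate 3 (step 0.889) and 8.62 in that same library labelled knockdown. H2-Oa (-0.50) and Clec10a (-0.80) had lower means. Mast cell genes (median 0.27, adjusted p = 0.506, Kit at 0.28), NF-kB and STAT signalling genes (median -0.10, adjusted p = 0.0647, Nfkbiz at 0.43) and genes of apoptosis and pyroptosis (median -0.10, adjusted p = 0.0647, Bcl2l11 at -0.45) were not called either. Without the library labelled knockdown replicate 3 the T and natural killer cell (4.13e-05), dendritic cell (0.0137), NF-kB (0.00169) and apoptosis lists (0.00771) were called lower. T and natural killer cell genes were also called without wild-type replicate 1 (0.00340), and apoptosis genes without replicate 3 (0.0432). Without the library labelled knockdown replicate 1, the medians were 0.04 for T and natural killer cell genes (adjusted p = 0.812), 0.16 for dendritic cell genes (0.148, with the test pointing up), -0.05 for NF-kB genes (0.415) and -0.05 for apoptosis genes (0.583).

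Collagen genes did not all move one way. The 20 collagen genes had a median log2 difference of -0.17, 13 lower and 7 higher, and the list was not called (adjusted p = 0.0887). Col1a1, the main scar collagen gene, was at 4705, 4302 and 5011 in wild type and at 2393, 4385 and 4160 in the libraries labelled knockdown (log2 difference -0.41, SE 0.27). Col11a1 was at -1.08, Col18a1 at -0.36, Col5a1 at -0.35 and Col8a1 at -0.37, and the basement membrane collagen gene Col15a1 was at 0.20. The collagen list was called lower without wild-type replicate 1 (adjusted p = 0.0366) and without the library labelled knockdown replicate 2 (0.0253) or 3 (0.0467). Without replicate 1 of that group its median was -0.07 (adjusted p = 0.567) and the log2 difference of Col1a1 -0.13.

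Myofibroblast genes were lower for 21 of 23 members (median -0.34, adjusted p = 0.000450, and 0.668 with an estimated correlation). Acta2, the smooth muscle actin gene that marks these cells, was at 1247, 1117 and 1471 against 620, 1023 and 1080 (log2 difference -0.53, SE 0.24), and Actg2 (-0.72), Tagln (-0.51), Thbs2 (-0.63) and Fap (-0.28) also had lower means. Meox1, a transcription factor gene of activated fibroblasts, went the other way (0.57, SE 0.13). With the heart muscle score of each library as a covariate the adjusted p of this list was 0.0732, and without the library labelled knockdown replicate 1 it was 0.0463, at a median of -0.15. Genes of matrix crosslinking and turnover were lower for 29 of 33 (median -0.27, adjusted p = 2.59e-05, and 0.668 with an estimated correlation), among them the protease genes Adamts4 (-0.70), Mmp19 (-0.79) and Mmp14 (-0.57). Without the library labelled knockdown replicate 1 their median was -0.11 (adjusted p = 0.0107). No member of the collagen, myofibroblast or crosslinking lists passed, whether over all genes or adjusted over the list alone.

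Genes of resting fibroblasts (14 of 20 higher, median 0.17, adjusted p = 0.0845) were not called, but Pi16, which marks fibroblasts of the adventitia, passed adjusted over the list alone as the only 1 of the 20, at 49.8, 45.8 and 44.6 against 101, 64.5 and 79.8. It did not pass when any single wild-type library was left out (0 of 20). Scn7a (0.34) and Abca8a (0.73) were also higher without overlap. For Scn7a the gap was about that of the steps. It was at 19.7 in wild-type replicate 3 (step 0.889) and 21.96 in the library labelled knockdown replicate 3 (step 0.998). Matrix glycoproteins and proteoglycans (median -0.11, adjusted p = 0.182) held members in both directions, such as Cilp (0.90), Mfap5 (0.33), the osteopontin gene Spp1 (-1.13) and Fbln2 (-0.49). The same held for matrifibrocyte genes (median 0.16, adjusted p = 0.484, Thbs4 at 0.86 and Acan at -0.84) and the TGF-beta pathway (median -0.11, adjusted p = 0.0887, Smad7 at 0.33 and Tgfbi at -0.60). Hyaluronan and inter-alpha-inhibitor genes, the family of Itih5 and its ligand, were not called (median -0.23, adjusted p = 0.1103), although the pentraxin gene Ptx3 was at 23.5, 23.5 and 20.03 against 10.7, 14.4 and 16.0. That list was called lower without wild-type replicate 1 (0.0287) or the library labelled knockdown replicate 3 (0.0266). Without the library labelled knockdown replicate 2, resting fibroblast genes were called higher (0.0236) and matrix glycoproteins (0.00516, also 0.0292 without wild-type replicate 1) and the TGF-beta pathway (0.00303) lower. Without replicate 1 of that group the medians were 0.15 for resting fibroblast (adjusted p = 0.125), -0.01 for matrix glycoprotein (0.850), -0.01 for TGF-beta (0.633) and -0.14 for hyaluronan genes (0.147).

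**Figure D2:**
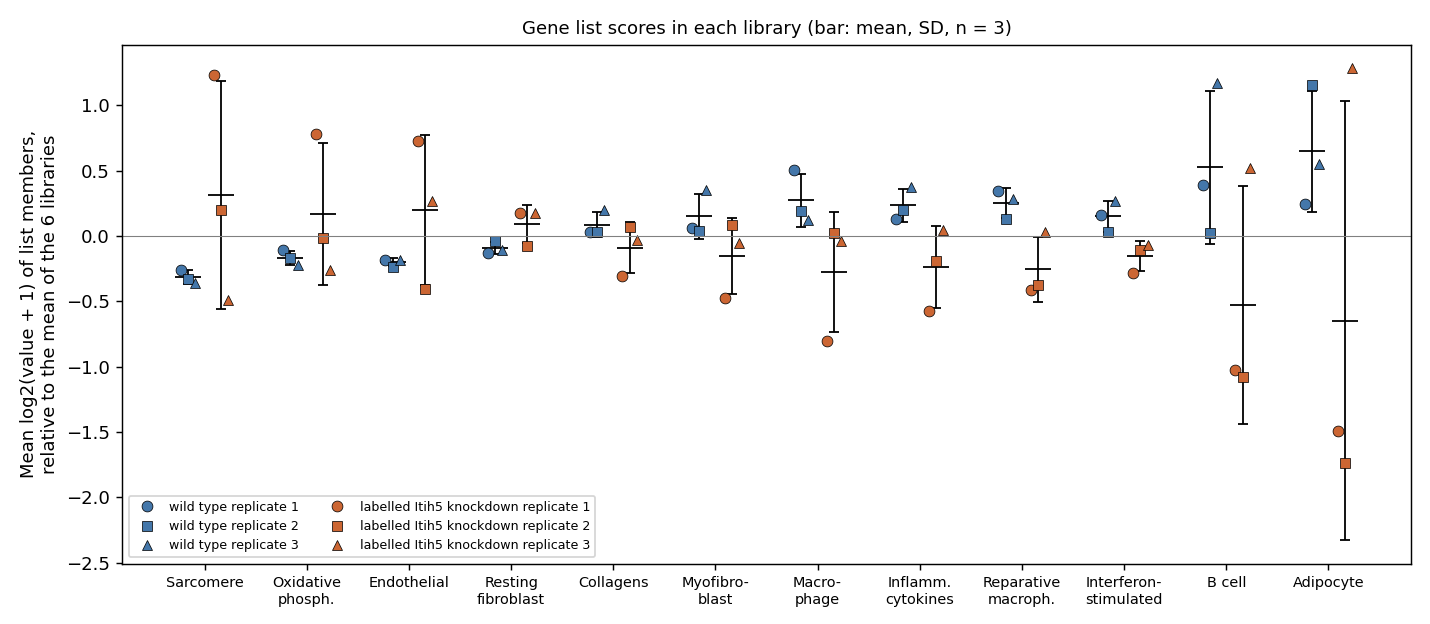
Mean log2(value + 1) of the members of 12 gene lists in each library, relative to the mean of the 6 libraries, with wild type in blue and the libraries labelled Itih5 knockdown in orange; symbols give the replicate number and bars the mean and SD of 3 libraries. The library labelled knockdown replicate 1 has the highest sarcomere score (1.24) and the lowest macrophage score (-0.80).

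Heart muscle genes were higher in the libraries labelled knockdown, above all in replicate 1. All 30 sarcomere genes had a higher mean (median 0.59, adjusted p = 1.87e-05), and the myosin gene Myh6 was at 265, 277 and 272 in wild type and 1214, 354 and 367 in the libraries labelled knockdown. Ttn (0.97) and Myl2 (1.04) were likewise higher without overlap, but only narrowly. From wild-type replicate 2 to the library labelled knockdown replicate 3, Ttn went from 7.48 to 7.98 and Myl2 from 1726 to 1743. The steps of these libraries, 0.932 and 0.998, differ by more in proportion. The sarcomere score was -0.26, -0.33 and -0.36 in wild type and 1.24, 0.20 and -0.49 in the libraries labelled knockdown, so the third of these had the lowest score of all 6. Oxidative phosphorylation genes (34 of 35 higher, median 0.33, adjusted p = 0.000238, Ndufb3 at 0.43), cardiac ion channel and calcium genes (19 of 20, median 0.27, adjusted p = 0.00815, Cacna1c at 0.82) and fatty acid oxidation genes (26 of 29, median 0.26, adjusted p = 0.0327, Cpt1b at 0.97) were called as higher. With an estimated correlation, the adjusted p was 0.692 for fatty acid oxidation and 0.668 for the other 3. Without the library labelled knockdown replicate 1, the sarcomere median was 0.14 and its adjusted p 0.0243, or 0.854 with an estimated correlation, and oxidative phosphorylation (median 0.02, adjusted p = 0.812), ion channel (0.10, 0.284) and fatty acid oxidation genes (-0.06, 0.148) were not called. Fatty acid oxidation genes were also not called without wild-type replicate 2 (0.0545) or 3 (0.114), nor ion channel genes without wild-type replicate 2 (0.0681), and 27 sarcomere genes passed over their list alone without the library labelled knockdown replicate 3, against 0 with all 6 libraries. Stress and fetal genes of heart muscle (median 0.40, adjusted p = 0.0647, Nppb at 0.71, called without wild-type replicate 3, at 0.0474, or the library labelled knockdown replicate 3, at 5.39e-06, with a median of 0.11 without replicate 1) and atrial and conduction genes (median 0.10, adjusted p = 0.564, Tbx3 at 0.36) were not called.

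Endothelial genes were higher for 25 of 28 members (median 0.46, adjusted p = 0.000450, and 0.668 with an estimated correlation), with Egfl7 at 0.72, Sox17 at 0.53 and Cldn5 at 0.84, while the tip cell gene Esm1 was at -0.37. The score was -0.18, -0.23 and -0.18 in wild type and 0.73, -0.40 and 0.27 in the libraries labelled knockdown, so replicate 2 of that group had the lowest of all 6. The call was lost without the library labelled knockdown replicate 1 (median 0.16, adjusted p = 0.148), and without replicate 2 of that group 22 members passed over the list alone, against 0. Lymphatic endothelial genes were not called (median 0.31, adjusted p = 0.0590), but Mmrn1 (0.95, SE 0.22) and the lymphangiogenic factor gene Vegfc (0.45, SE 0.13) passed adjusted over the list alone, as 2 of 9, and 0 did without wild-type replicate 1 or 2 or the library labelled knockdown replicate 1 or 3. The count was also 0 among genes with a mean of at least 5 and on recovered whole-number TPM. Mmrn1 had low values, at 1.93, 1.83 and 2.65 against 4.59, 3.85 and 6.99. Pericyte and smooth muscle genes (median 0.06, adjusted p = 0.993, Pdgfrb at -0.21), Schwann cell and neuronal genes (median -0.01, adjusted p = 0.996, Cnp at -0.47) and glycolysis and hypoxia genes (median -0.02, adjusted p = 0.993) were not called. Lymphatic endothelial genes were called without wild-type replicate 3 (0.0204) or the library labelled knockdown replicate 3 (0.0405), and had a median of 0.18 without replicate 1 (0.148). For glycolysis and hypoxia genes the mean (0.08) and the test pointed up and the median down, and for Schwann cell genes the mean (0.04) pointed up and the test and median down. Ankrd37, a hypoxia-induced gene, passed adjusted over the glycolysis and hypoxia list alone (0.99, SE 0.20), the only 1 of its 27, and did not when any single wild-type library was left out (0 of 27).

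Cell cycle genes were lower for 32 of 34 members (median -0.20, adjusted p = 1.99e-05), including the replication genes Mcm2 (-0.38), Mcm5 (-0.40), Mcm6 (-0.28) and Rrm2 (-0.40). Their scores overlapped between the groups, at 0.24, -0.06 and 0.12 in wild type and -0.03, -0.29 and 0.02 in the libraries labelled knockdown. Without replicate 2 of that group, which had the lowest score, the adjusted p was 0.0326. Cytosolic ribosomal protein genes were lower for 35 of 36 (median -0.17, adjusted p = 0.000450, Rps3 at -0.32), a call lost without the library labelled knockdown replicate 1 (median -0.04, adjusted p = 0.101). With an estimated correlation both lists had an adjusted p of 0.668. Immediate early genes, which respond to handling of tissue, were not called (median 0.05, adjusted p = 0.159, Nr4a2 at 0.54), except without the library labelled knockdown replicate 2 (0.0353).

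Markers of tissues around the infarct differed between libraries of the same label. Epicardial and mesothelial genes had scores of 0.29, 0.43 and 0.48 in wild type and -1.38, -0.60 and 0.77 in the libraries labelled knockdown (median -0.97, adjusted p = 0.00540, Krt8 at -1.09). Adipocyte genes, not called (median -0.91, adjusted p = 0.0988), showed the same layout, and were called lower without wild-type replicate 1 (0.0436) or the library labelled knockdown replicate 3 (2.18e-06); without replicate 1 of that group the median was -0.38 (0.148). Cfd, the adipsin gene, was at 285, 810 and 402 in wild type and 1.44, 3.47 and 852 in the libraries labelled knockdown. Erythroid genes were higher (9 of 9, median 1.09, adjusted p = 0.00815), the haemoglobin gene Hba-a1 being at 247, 105 and 83.5 against 959, 119 and 386. Skeletal muscle genes were higher for 7 of 7 (median 0.45, adjusted p = 0.0470, Mylpf at 0.45). All 3 called lists had an adjusted p of 0.668 with an estimated correlation, and all 3 calls were lost without the library labelled knockdown replicate 1 (0.101, 0.225 and 0.0542, at medians of -0.32, 0.56 and 0.41). The skeletal muscle call was also lost without wild-type replicate 1 (0.0603), 2 (0.0680) or 3 (0.0532) or the library labelled knockdown replicate 2 (0.126), and it held under only 8 of 18 alternatives. Among genes with a mean of at least 5 the list had too few members to be tested. Mylpf, at 1.94, 2.80 and 2.68 against 3.46, 2.88 and 4.99, lay within a few rounding steps.

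Mitochondrially encoded genes took 13.8%, 11.5% and 10.9% of all values in wild type and 32.6%, 14.8% and 20.2% in the libraries labelled knockdown, a mean of 12.05% ± 1.54 (SD, n = 3) against 22.6% ± 9.13 (SD, n = 3; exact permutation p = 0.1, the smallest possible). mt-Co3 was at 713, 385 and 347 against 3926, 805 and 1594. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 6 libraries. The libraries labelled knockdown were also less alike than the wild-type libraries, and on log2 values across the 14025 tested genes replicate 2 (0.9704 against 0.9696) and replicate 3 (0.977 against 0.962) correlated slightly better on average with wild type than with their own group.

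In all, 21 of the 40 lists were called with the preset correlation, 14 lower and 7 higher, and 15 list members passed adjusted over the list alone, against 0 over all genes. No list was called with an estimated correlation (smallest unadjusted p = 0.0817, smallest adjusted p = 0.668), and none with the self-contained fry test (smallest adjusted p = 0.1603). Of the 10 ways of dividing the 6 libraries into 3 and 3, the real one included, 6 gave at least 21 called lists, and the highest count was 27. List scores did not overlap between the groups for 7 of the 40 lists, all of them called, where chance gives 10%. These were the crosslinking, macrophage, cytokine, reparative macrophage, interferon-stimulated, engulfment and skeletal muscle lists. The scores of the other called lists overlapped. Without the library labelled knockdown replicate 1, 13 lists were called, all 13 among the 21 and in the same direction, 12 lower and 1 higher. Without wild-type replicate 2, 4 lists were called higher. The 15 members became 1 and 2 without wild-type replicates 1 and 3, and 68 and 127 without the libraries labelled knockdown replicates 2 and 3.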

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

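Whole-number TPM, the heart muscle covariate and the count of members past the threshold over their own list were chosen after the data were seen, and all other alternatives before. Itih5 was higher by 0.06 to 0.52 on the log2 scale in the libraries labelled knockdown under 19 alternatives, with adjusted p from 0.313 to 0.953. The macrophage (adjusted p up to 0.000513), inflammatory cytokine (up to 0.00842) and reparative macrophage lists (up to 0.00479) were called lower under all 19 that kept the preset correlation. With an estimated correlation 0 lists were called in either direction, and the adjusted p of the myofibroblast, macrophage, cytokine and reparative macrophage lists was 0.668. With fry, 0 lists were called, with 0.593 for the myofibroblast and macrophage lists and 0.439 for the cytokine and reparative lists. These tests allow for how genes of a list vary together. Depth is unknown, so its effect was not tested.

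Leaving out libraries, 0 to 13 genes were lower and 0 higher. Lists called ranged from 13 to 30 (1 to 9 higher, 12 to 21 lower), the collagen list from 0.0253 to 0.567, and members past the threshold over their own list from 1 to 127. These fits have fewer samples, and the cause was otherwise not tested. Members past the threshold over their own list numbered 15 as reported, 24 with quantile normalization, 6 with no intensity trend, 39 with quality weights, 1 with whole-number TPM and 6 with the muscle covariate, and the cause was not tested. Whole-number TPM moved the median of all genes to -0.13 and gave 12 genes higher and 10 lower. All 22 had identical whole values, between 1 and 4, within each group, so these calls follow from the rounding. With the muscle covariate 11 lists were called, 1 higher, the myofibroblast (0.0732), neutrophil (0.0705), complement (0.157), ribosomal protein (0.224), endothelial (0.114), mesothelial (0.602), erythroid (0.224), ion channel (0.997) and skeletal muscle calls (0.186) were lost, and the sarcomere list has no value because it defines the covariate.

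The skeletal muscle call was also lost with pseudocount 0.1 (0.0527), no filter (0.0777), mitochondrial genes left out (0.0751) and the 50 most abundant left out (0.0568). The neutrophil call was lost with a mean of at least 5 (0.0570), the mesothelial with whole-number TPM (0.143), the erythroid with quality weights (0.312), and the fatty acid oxidation call with mitochondrial genes left out (0.0634) and quality weights (0.418). Calls were gained for lymphatic genes with no filter (0.0291), quantile normalization (0.0399), the 50 most abundant left out (0.0344), quality weights (0.0357) and whole-number TPM (0.0167). They were gained for stress genes with a mean of at least 5 (0.0337), quantile normalization (0.0399) and whole-number TPM (0.0150), and for T cell genes with no filter (0.0291) and mitochondrial genes left out (0.0425). Adipocyte genes gained a call with mitochondrial genes left out (0.0457), and resting fibroblast genes with quantile normalization (0.0371) and whole-number TPM (0.0474). The cause was not tested.

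Replicate numbers were shared between the groups, but the correlations of same-numbered libraries around their group means (0.056, 0.061 and 0.143) were not all above 0.1, so the numbers were not taken as pairs, although 5 of 6 libraries correlated best with their own number, a hint from the data. With the replicate block 0 genes were higher and 0 lower, 25 lists were called and 55 members passed over their own list. The Schwann cell list turned direction under the block (0.932), and the lymphatic (0.0422), stress (0.0223), T cell (0.0148) and adipocyte lists (0.0370) gained a call.

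Other lists that turned direction were almost all uncalled in both fits, and the cause was not tested. They were Schwann cell genes with pseudocount 5 (0.9995), median-of-ratios scaling (0.970), whole-number TPM (0.637) and fry (0.867), and atrial genes with no filter (0.939) or the 50 most abundant genes left out (0.871). Glycolysis and pericyte genes turned with no filter (0.992 for both), mitochondrial genes left out (0.956 and 0.943) and no intensity trend (0.979 for both), and pericyte genes with the 50 most abundant left out (0.997). With quality weights, matrix glycoprotein (0.777), glycolysis (0.777) and dendritic cell genes (0.836) turned, and with whole-number TPM dendritic cell (0.913) and glycolysis genes (0.931). With the muscle covariate, dendritic cell genes were called higher (0.0194) and fatty acid oxidation genes lower (0.00429), and T cell (0.224), stress (0.439), oxidative phosphorylation (0.0685), glycolysis (0.0732) and NF-kB genes (0.997) turned uncalled. Some fit with a library left out turned matrifibrocyte (over the 6 such fits 0.262 to 0.952), atrial (0.388 to 0.952), pericyte (0.415 to 0.852), Schwann cell (0.487 to 0.896), glycolysis (0.230 to 0.914), dendritic cell (0.0137 to 0.982), fatty acid oxidation (3.04e-05 to 0.148), adipocyte (2.18e-06 to 0.896) and mast cell genes (0.105 to 0.858). Among named genes, Itih4 turned without the library labelled knockdown replicate 2 (over the 6 fits -0.740 to 0.0817) and with the muscle covariate (0.136), mt-Nd3 without replicate 1 of that group (-0.174 to 0.927) and with the covariate (-0.209), Kcnj3 with the covariate (-0.0133) and Ddx3y with whole-number TPM (-0.0281). Over all lists and alternatives, 684 values kept direction and side of the threshold, 74 lost a call, 39 gained it and 40 turned.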

Other observations

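The zinc finger and nuclear RNA gene sets, kept from several sets and gene properties looked at, and every test below except the counts over other divisions of the libraries were chosen after the values were seen; the list test on recovered whole-number TPM was chosen after the values but before its own result. Genes of zinc finger transcription factors, 385 named Zfp, Zkscan, Zscan or Zbtb, of which 2 stand in the fixed lists, had a median log2 difference of 0.11 in the libraries labelled knockdown, with 273 higher and 112 lower. These counts rest on the deposited scale. On recovered whole-number TPM, 271 of the 385 lay above the median of all genes, which was itself at -0.13. No p-value is given for the zinc finger genes, since the set was picked from these values. Their mean score lay between -0.08 and -0.03 in wild type and between 0.05 and 0.08 in the libraries labelled knockdown. Of 8 long non-coding RNAs retained in the nucleus, a set also picked after the values were seen, none passed. All 8 had a higher mean in the deposited values, but 5 overlapped between the groups, with log2 differences from 0.02 for Rian to 0.43 for Meg3. Those of Rian, Tug1 (0.08) and Pvt1 (0.12) were smaller than the move of the median of all genes, to -0.13, on whole-number TPM. Their direction may therefore rest on the scale between libraries. The 3 that did not overlap were Neat1 at 56.5, 67.5 and 32.6 against 118, 100.3 and 107, Malat1 at 95.6, 132 and 80.5 against 175, 140 and 167, and Airn.

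Whether the grouping by label stands out was asked by dividing the 6 libraries into 3 and 3 in all 10 ways, too few for a share under 0.05. With 0 genes past the threshold in the real division, all 10 reached that count, and the highest other division had 1. At an unadjusted p under 0.05 the real division had 2081 genes, a count reached by 1 of 10, and the highest other had 802. For lists called with the preset correlation, 6 of 10 divisions reached the real count of 21, the highest other having 27, which points to a structure of the samples in which lists of correlated genes differ between libraries whatever their label.

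Macrophage, inflammatory cytokine and reparative macrophage genes were lower in the libraries labelled knockdown, the mean difference of the 3 list scores being -0.51. Without the library labelled knockdown replicate 1 all 3 lists stayed lower, with a difference of -0.34. That library therefore does not make up the whole difference. Whether the rest exceeds the spread between libraries is not settled. The largest adjusted p of the 3 lists was 0.000297 with the preset correlation, which called at least 21 lists in 6 of 10 divisions. With an estimated correlation the adjusted p was 0.709 to 0.823. More heart muscle in the piece sampled stays open as the whole cause. With the muscle score held fixed the difference was -0.29 (95% interval -0.52 to -0.05), on only 3 residual degrees of freedom. This cannot decide it, because the score measures muscle content imperfectly and is high mainly in 1 library (1.24). The 3 lists were also put together after their values were seen. A factor shared by all genes of a library nearly cancels in a test against the other genes, so it would not lower these lists. On recovered whole-number TPM, with such a factor undone, the largest adjusted p was 0.00842 with the preset correlation. Any other part of the authors' adjustment is not known and stays open. Other differences in tissue make-up stay open too. So does an effect of the labelled knockdown on macrophages, an untested hypothesis that macrophage counts in sections of the same hearts would check.

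Itih5 was not lower in the libraries labelled knockdown. A lack of precision to show a fall to 50% is argued against, since the lower limit of the 95% interval was -0.39. Such a fall would give -1, or a slightly smaller change because 1 was added to each value. A smaller fall is not excluded. Labels swapped between the groups, or a single wrong label, stay open: 0 wild-type libraries but 2 of the 3 labelled knockdown, replicates 2 (0.9704 against 0.9696) and 3 (0.977 against 0.962), correlated better with the other group than with their own, and correlations between libraries are the same whether or not both labels are swapped. More fibroblasts, which could hide a lower level per cell, cannot be told apart from no change, because relative to the resting fibroblast score the difference was 0.0728 with an interval from -0.72 to 0.87. A knockdown limited to some cells, or one that acts on the protein, was not tested.

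For the zinc finger genes, a trend on transcript length, GC content and abundance, fitted on the other genes, was removed. The median was then 0.0659 (bootstrap 95% interval 0.04 to 0.11). That bootstrap resamples genes, leaves out the spread between libraries and uses a set picked from these values. It therefore cannot decide whether such a trend is the whole cause. Across 6 versions of the trend the median ran from 0.06 to 0.09, and against 30 matched genes each it was 0.07. An interpolated fit gave 0.01. It was set aside, after that value was seen, because it also moved the median residual of all genes to -0.05. The authors' adjustment stays open: on recovered whole-number TPM these genes lay 0.13 above the median of all genes, a distance that a factor shared by all genes hardly changes, and their own median was 0. More nuclear RNA in the libraries labelled knockdown may account for both sets and cannot be told apart from a change in transcription. The nuclear RNAs gave p = 0.0766 by camera with an estimated correlation. That value decides nothing, because only 8 were tested and they were picked after the values were seen.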
